A study of Mus musculus with 2 samples.

How the data were processed

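RNA of interscapular brown fat from WT and DKO mice was measured on 2 Agilent whole mouse genome arrays with reversed dyes. Per the labels' protocols, RNA was amplified and labelled with Cy3 or Cy5, 750 ng of cRNA per dye was mixed, and hybridisation ran for 17 hours. The labels give the starting total RNA as 500 ng in one place and 100 ng in another. Whether the RNA of the 4 mice of a genotype was pooled, and whether both arrays used the same extracts, is not given in the sources used here. The arrays were therefore counted as 1 replicate per genotype.

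The authors extracted the images with Agilent Feature Extraction 7.5 at default settings, per the labels and the submitters' processing notes. Per the file headers, the deposited spot files hold mean, median and local background signals as intensity on a linear scale, not yet normalised. The deposited files also hold log10 ratios of red over green, which the software made after spatial detrending and dye normalisation, per the file headers. A p-value of each log ratio from the software's error model, which covers measurement error on one array, is deposited beside it per the file headers. The flags for outliers, saturation and signal well above background (2.6 background SDs per the file headers) were used as deposited. The deposited series value table holds log2 ratios: its columns matched red over green from the scanner files within 0.001 for 40962 of 41001 and 41101 of 41141 values. Both columns had a median of 0. The labels name Rosetta Resolver for later processing, and which of its steps shaped that table is not given in the sources used here.

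Mean signals were corrected with normexp against the median local background with an offset of 50, then loess-normalised within each array with control spots at weight 0, in limma 3.58.1 under R 4.3.3. The offset shrinks log ratios of dim probes, so the software's ratios are given beside some values. The sign was turned on the array with DKO in Cy3 and both arrays were averaged. Spots marked as outliers were left out (171 and 29 probe spots), saturated spots were kept (12 and 14), and replicate spots of a probe were averaged, which left 40979 probes. Median mean signals were 113 in Cy3 and 130 in Cy5 on the array with DKO in Cy5, and 107 and 108 on the other, over local backgrounds of 72, 58, 70 and 57. With 2 arrays, their number limits the precision.

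Probes were named through a RefSeq gene table of assembly GRCm38.p6, used for names and neighbourhood only: 18314 matched by accession, 1498 by symbol, 933 by an older symbol and 20234 not at all. Those without a match kept the name in the file. A gene was represented by its probe of highest average intensity, measured probes first. A gene counted as measured if a genotype was well above background on both arrays, which held for 28677 genes and transcripts, 14101 of them with a symbol.

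The rules below were set before the data were examined. A gene was called where the mean was at least 2-fold, each array went the same way by at least 1.5-fold, and the probe was well above background in the higher genotype on both arrays. The same rule with the sign unturned gauged dye bias. No called gene was below background in the other genotype or saturated. For 32 gene lists, the median of measured members was placed among 10000 random lists of the same size, drawn with replacement from measured genes with a symbol in 20 intensity bins; lists with under 5 measured members got none. This percentile describes these preparations and is no test. Named genes were Rora, every measured core clock gene, the 12 highest and 12 lowest called genes with a symbol, up to 4 called members per list or else the 2 brightest, and up to 6 called genes near the targeted loci. Other genes named were chosen after their values were seen. The level of 1 gene that the rule names is not reported here.

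The rule was tested on simulated arrays of 41174 probes. It recovered 4 of 50 probes changed 2-fold, 31 of 50 changed 3-fold, 30 of 50 changed 4-fold and 47 of 50 changed 8-fold, and called 0 of 40974 unchanged probes. Changed probes were drawn only from those with a mean background-subtracted signal above 20, so the recovery does not cover the dimmest probes. Of 100 simulated lists of 20 unchanged members, 3 lay outside the central 95%, and of 100 lists shifted by 0.1, 100 did. The simulated noise of the log ratios was taken from probes above an average log2 intensity of 9 and applied to all probes. It was set below the level that would account for all the spread between arrays there. The recovery and the 0 false calls hold for that noise and do not bound errors in these data. Alternatives covered the offset, the software's ratios, median signals, median centring, loess on detected probes, the dim filter, the probe rule, size thresholds, the error model, the series value table and each array alone. Scripts ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.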

Results

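Brown adipose tissue burns lipid to make heat. In this series, RNA from the interscapular brown fat of wild-type mice (WT) was set against RNA from double-knockout mice (DKO) whose lost genes include the nuclear receptor gene Rora. The labels name 4 male mice per genotype on the C57BL/6 background, 2 to 3 months old, collected near circadian time 20. Both genotypes were hybridised together on each of 2 whole mouse genome arrays, with DKO in Cy5 and WT in Cy3 on one and the dyes reversed on the other. Each array carried 41534 probe spots for 41174 distinct probes. On the array with DKO in Cy5, 80.0% of probe spots were well above background in Cy3 and 85.4% in Cy5, and on the array with DKO in Cy3 these shares were 77.6% and 80.2%. The 2 arrays were treated as one RNA preparation per genotype hybridised in both dye orientations, so each genotype had 1 replicate and no test was possible. Values are log2 ratios of DKO over WT, as the mean of both arrays ± SD (n = 2 arrays). That SD holds dye effects and measurement error. If both arrays used the same extracts, which is not given, it holds no spread between animals, and it was not taken as a measure of that spread.

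Rora was examined first, since it bears on the labels. Rora (gene ID 19883) read −0.38 ± 0.04 and was lower in DKO on each array. It did not reach the 2-fold size rule and stayed well above background in DKO. A second Rora probe read −0.47 ± 0.10. The scanner software's own log ratios, which do not carry the added signal offset, gave −0.96 ± 0.07 for the first Rora probe and −1.52 ± 0.14 for the second. Which part of the gene was deleted, and whether the probes lie inside it, is not given in the sources used here, and a probe outside the deleted part would check nothing.

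**Figure D1:**
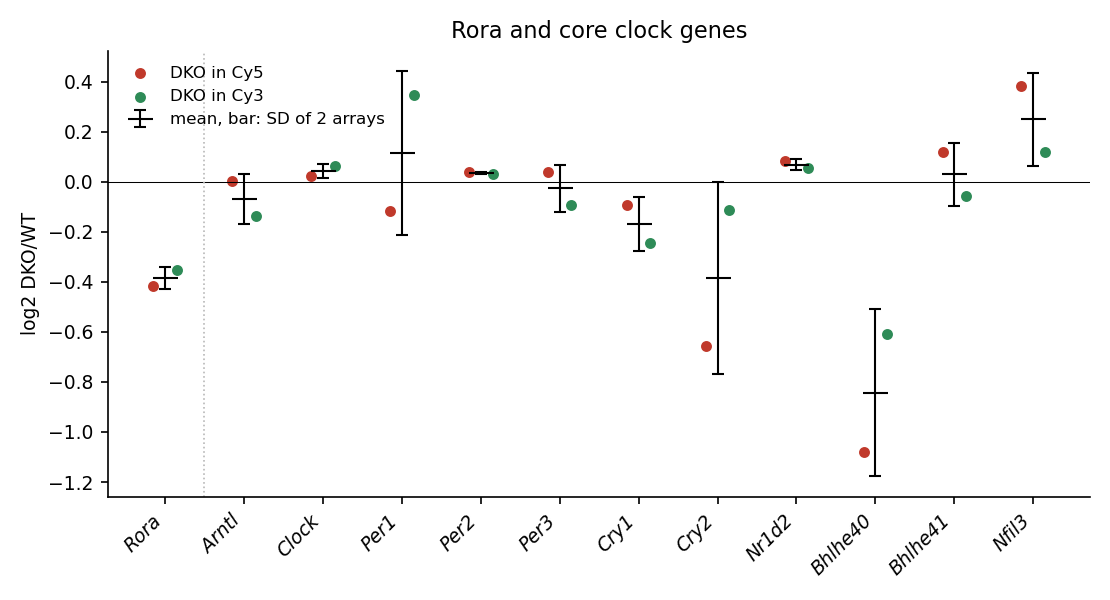
Log2 ratio of DKO over WT for Rora and the 11 measured core clock genes. Points are the single arrays, dashes the mean and bars the SD of both arrays. Rora lies below 0 on both arrays, while among the clock genes Bhlhe40 lies lowest at −0.84.

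Rora binds promoters of core clock genes, so the clock lists were examined next. No measured core clock gene passed the size rule. In the activator arm, Arntl read −0.07 ± 0.10 and Clock read 0.04 ± 0.03, while Npas2 and Arntl2 were not well above background. Of the repressor arm, Nr1d1 was not well above background and Ciart matched no probe in use, so neither was examined. In the repressor arm, Per1 (0.12 ± 0.33), Per2 (0.03 ± 0.00), Per3 (−0.03 ± 0.09) and Nr1d2 (0.07 ± 0.02) lay near 0. The Nr1d2 probe was matched by a RefSeq accession, while its description in the file names thyroid hormone receptor alpha, so that value may belong to another transcript. The dim probes of Cry1 (−0.17 ± 0.11) and Cry2 (−0.38 ± 0.38) read −0.63 ± 0.54 and −0.74 ± 0.82 with the scanner software's ratios. Nfil3 read 0.25 ± 0.19 and Bhlhe41 read 0.03 ± 0.13. Bhlhe40, a transcriptional repressor, had the lowest value of the group at −0.84 ± 0.33. The median of the 9 measured repressor-arm genes was 0.03, at percentile 90.7 of random lists matched on intensity. Among clock outputs, Dbp read −0.08 ± 0.05 and Por read 0.25 ± 0.08, and the list's median of 0.06 lay at percentile 96.9, with −0.09 on the array with DKO in Cy5 and 0.30 on the other. The 25 measured genes with reported ROR response elements had a median of −0.04, at percentile 0.99, and only Elovl3 among them passed the rule. That percentile moved to 17.5 with the scanner software's ratios, to 17.8 on the array with DKO in Cy3 alone and to 72.5 with median centring, where the median turned to 0.06. Both other dim filters also brought it inside the central 95%. Both arrays sample one circadian time, so phase and amplitude were not measured.

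Across 28677 measured genes and transcripts, 29 were at least 2-fold higher in DKO and 7 were at least 2-fold lower. On the array with DKO in Cy5 alone 32 were higher and 38 lower, and on the other 55 and 9, so the excess of higher calls was absent from one array. After the sign was turned, the arrays correlated weakly, with r of 0.08 over measured genes with a symbol. For the 2076 of these with an average log2 intensity of at least 9, r was 0.24. The mean ratio had an SD of 0.14 over measured genes with a symbol, against 0.13 in the dye direction. Of these genes, 19.2% lay above 0 on both arrays and 19.2% below 0 on both. The highest named gene was Cyp2b9, a cytochrome P450, at 2.39 ± 0.09 or 5.24-fold. It was followed by the metallothionein Mt2 (1.90 ± 0.27), Dio2, the deiodinase that activates thyroid hormone (1.89 ± 0.32), Fbxo31 (1.82 ± 0.04) and Cyp2b13 (1.76 ± 0.40). Pck1, which feeds gluconeogenesis in liver and glycerol synthesis in fat, rose by 1.59 ± 0.06. The remainder of the 12 highest were Gmpr (1.55 ± 0.07), Ckmt2 (1.42 ± 0.28), St3gal5 (1.39 ± 0.13), Depp1 (1.35 ± 0.09), Pdk4 (1.34 ± 0.11) and Acot1 (1.21 ± 0.16). The 7 lower genes were the fructose transporter Slc2a5 (−1.57 ± 0.10), the prostaglandin receptor Ptger3 (−1.40 ± 0.20), Acss2 (−1.19 ± 0.28), the insulin receptor adaptor Grb14 (−1.17 ± 0.01), Lmo1 (−1.11 ± 0.07), the hormone gene Lep (−1.08 ± 0.42) and Nudt4 (−1.01 ± 0.56). Of the 29 higher, 5 had no gene symbol, among them the highest value of all (probe A_51_P279437, 2.64 ± 0.18). The same rule applied to dye instead of genotype called 1 gene. The scanner software's ratios called 53 higher and 28 lower, a higher share of 65.4% against 80.6%, and included all 29 and all 7; the dye direction then called 16. Second probes gave smaller values for several called genes, including Cyp2b9 (0.52 ± 0.25) and Cyp2b13 (0.06 ± 0.09), and the Cyp2b family, metallothioneins and acyl-CoA thioesterases have close paralogs whose cross-hybridisation was not resolved.

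**Figure D2:**
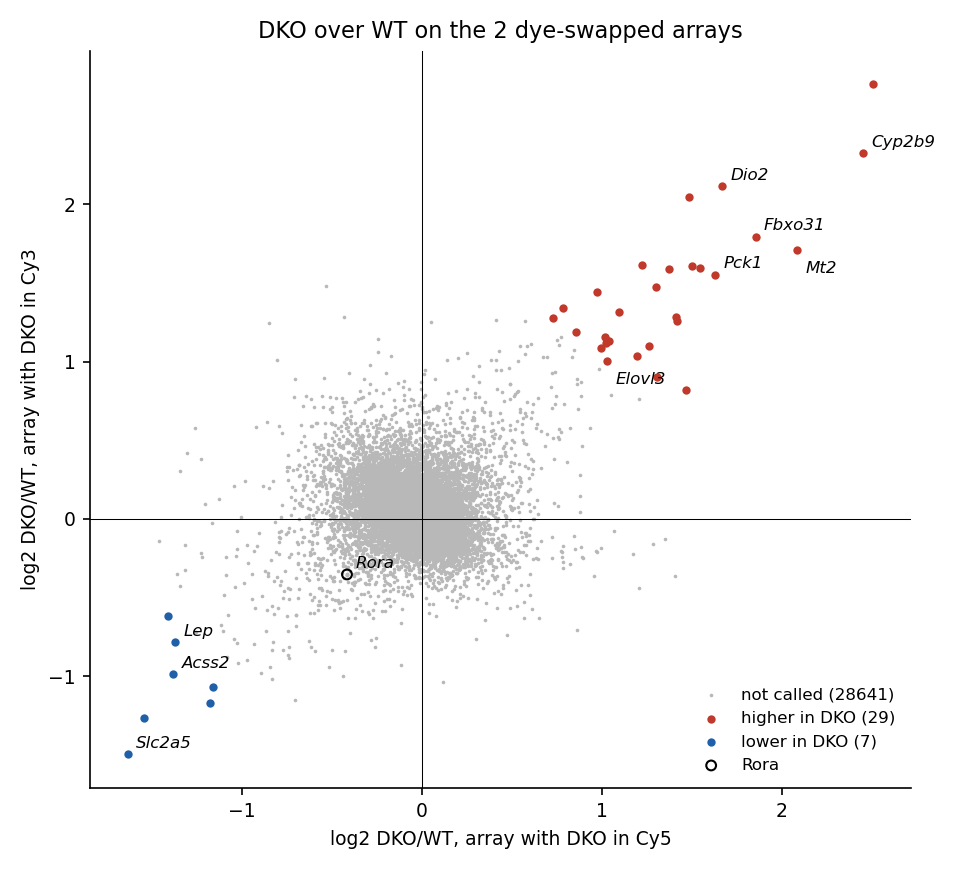
Log2 ratio of DKO over WT on the array with DKO in Cy5 (horizontal) against the array with DKO in Cy3 (vertical), one point per measured gene or transcript. Red points are the 29 called higher, blue points the 7 called lower and the open circle Rora.

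Lists of thermogenesis and lipid burning had medians above 0, though most members were not called. In the list of brown adipocyte thermogenesis and identity, 6 of 38 measured genes rose, none fell and 32 did not pass; 16 lay above 0 on both arrays and 4 below 0 on both. The 4 largest were Dio2, Fbxo31, Ckmt2 and Slc27a2 (1.09 ± 0.10). Other Slc27a2 probes read 0.37 ± 0.08 and 0.06 ± 0.06. Ckmt2 is annotated in the file as a sarcomeric creatine kinase, so its value need not come from brown adipocytes alone. The list's median was 0.07, at percentile 99.98, with 0.09 on the array with DKO in Cy5 and 0.14 on the other, and it was 0.11 with the scanner software's ratios. In fatty acid oxidation, Pdk4 and Acot1 rose among 29 measured genes, 16 lay above 0 on both arrays and 1 below, and the median was 0.19, at percentile 100.0. On the array with DKO in Cy5 alone that median was 0.08, at percentile 97.2, inside the central 95%. None of the 43 oxidative phosphorylation genes passed, with Atp5b at 0.31 ± 0.44 and Uqcrh at 0.10 ± 0.23. Their median was 0.09, at percentile 99.5, and on the array with DKO in Cy3 alone it was 0.00, at percentile 38.9. Skeletal muscle markers also stood higher, with Eno3 (1.21 ± 0.33) and Mb (1.004 ± 0.39) called among 27 measured and a median of 0.25, at percentile 100.0. Brown fat and muscle share part of these transcripts, and the muscle median was 0.12 on one array and 0.56 on the other.

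The list of fatty acid and triglyceride synthesis genes was on the whole lower in DKO, but its triglyceride-assembly members went both ways. Of 27 measured genes, Acss2, which makes acetyl-CoA from acetate, fell, and Elovl3, a fatty acid elongase of brown fat, rose by 1.02 ± 0.02. The other 25 did not pass, but 17 of the 27 lay below 0 on both arrays and 4 above 0 on both. Among genes of triglyceride assembly, Gpam (0.52 ± 0.14) and Dgat2 (0.32 ± 0.25) lay above 0 on both arrays and Lpin1 (−0.49 ± 0.21) below. Dgat1 (0.16 ± 0.63) and Agpat2 (−0.07 ± 0.74) differed in sign between arrays. The lower median therefore does not speak for triglyceride assembly. The list's median was −0.46, at percentile 0.0, with −0.62 on the array with DKO in Cy5 and −0.21 on the other. Cholesterol synthesis and efflux had no called gene among 21, with Pmvk at −0.60 ± 0.36 and Hmgcs1 at 0.19 ± 0.12, and a median of −0.11, at percentile 0.0. The Hmgcs1 probe was likewise matched by accession, and its description names pre B-cell leukemia transcription factor 1. Markers shared by all adipocytes had a median of 0.00, at percentile 50.6, with −0.10 on the array with DKO in Cy5 and 0.22 on the other. Its brightest members, Fabp4 and Gpd1, were saturated, so their ratios are not given, and without saturated genes the median was 0.02, at percentile 79.1. Among 14 measured genes enriched in white adipocytes only Lep was called, and the median was −0.03, at percentile 3.46.

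**Figure D3:**
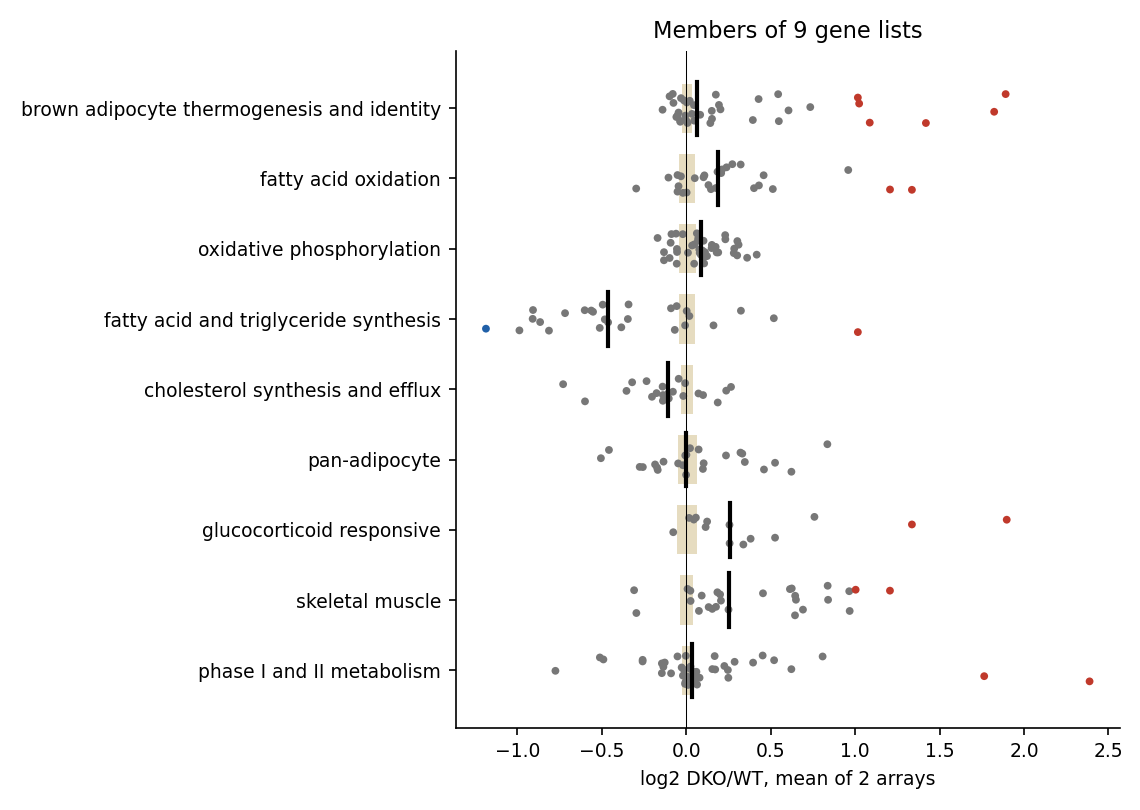
Log2 ratio of DKO over WT (mean of 2 arrays) for the measured members of 9 gene lists. Points are genes, red if called higher and blue if called lower, black bars are list medians and shaded bands hold the central 95% of medians of random lists matched on intensity. The fatty acid and triglyceride synthesis median lies at −0.46 and the fatty acid oxidation median at 0.19.

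Glucocorticoid-responsive genes were higher as a group, with Mt2 and Pdk4 called among 14 measured, none below 0 on both arrays, and a median of 0.26, at percentile 100.0. The thyroid hormone and adrenergic list had Dio2 called among 21 measured, with a median of 0.04, at percentile 98.8. In phase I and II metabolism, Cyp2b9 and Cyp2b13 rose among 45 measured, and the median was 0.03, at percentile 99.4. None of 23 heat shock and unfolded protein response genes passed, with Hspa8 at 0.26 ± 0.58, Hspd1 at 0.10 ± 0.15 and a median of 0.08, at percentile 99.8. In glycolysis and gluconeogenesis only Pck1 was called among 20, and the median was −0.00, at percentile 44.5. The heat shock median lay inside the central 95% of random lists on the array with DKO in Cy5 alone. The medians of the thyroid and of the phase I and II lists lay inside it on each array alone, so neither stood apart on a single array. Of the 29 lists given a percentile, 12 lay outside the central 95%, where independent genes would put 1.45, and genes of one pathway are not independent.

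Ratios of markers of other cell types showed little difference. The background filter does not show that a probe reads its own transcript. It passed the skin genes Krt5 and Lor and the liver gene Alb (average log2 intensities 8.77, 8.64 and 8.80). A probe that reads other signal can give a ratio near 0 in any cell mix. The medians below therefore do not show that the cell makeup was alike. Nothing was called among 26 macrophage and myeloid genes (median 0.02, percentile 96.1; Lyz2 0.20 ± 0.10, Fcer1g 0.02 ± 0.16) or 23 T cell genes (median 0.02, percentile 96.2; Cd3e 0.00 ± 0.05, Icos 0.01 ± 0.04). The 14 B cell genes (median −0.00, percentile 44.9; Cr2 −0.01 ± 0.15, Fcer2a 0.06 ± 0.08) and 14 endothelial genes (median −0.01, percentile 35.1; Flt1 0.16 ± 0.43, Kdr −0.20 ± 0.02) were likewise uncalled. So were 17 nerve and Schwann cell genes (median 0.01, percentile 65.2; Pmp22 −0.17 ± 0.11, Gfra3 0.02 ± 0.18) and 6 erythroid genes (median −0.03, percentile 18.3; Hba-a1 −0.46 ± 0.10, Car1 0.03 ± 0.01). Fibroblast and matrix genes had a median of −0.04, at percentile 2.1, with Sparc at −0.16 ± 0.37 and Dcn at −0.04 ± 0.05, and that percentile entered the central range in most alternative settings. Liver proteins (median −0.00, percentile 41.6; Alb 0.18 ± 0.04, Mup1 −0.16 ± 0.16) and skin genes (median 0.01, percentile 74.2; Krt5 0.01 ± 0.02, Lor 0.03 ± 0.17) gave no called gene. Inflammation (median 0.01, percentile 67.1; Hp −0.16 ± 0.69, Nfkbia 0.12 ± 0.35), immediate early genes (median 0.02, percentile 82.3; Junb 0.04 ± 0.62, Jund 0.03 ± 0.09) and cell cycle genes (median 0.02, percentile 80.5; Pcna 0.17 ± 0.22, Mcm6 0.00 ± 0.02) gave none either. Nuclear receptors and coregulators had a median of 0.01, at percentile 57.2, with Pparg at −0.02 ± 0.00 and Esrra at 0.15 ± 0.56. The sex-linked genes Xist (0.04 ± 0.07) and Eif2s3y (0.03 ± 0.51) did not differ by the size rule. The labels name only male mice, yet the probe of Xist, a transcript of female cells, counted as measured. Its average log2 intensity was 8.38, against 8.32 for Eif2s3y. What the Xist probe reads was not resolved, so these ratios do not check the sex label.

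Knockout alleles can bring flanking DNA of another strain, so genes beside the targeted loci were counted. None of 374 measured genes within 10 Mb of the targeted loci was called, against 31 of 13725 elsewhere. At the share elsewhere, 0.84 called genes would be found in that window, so these counts cannot show a deficit. The scanner software's ratios called 1 gene in the window, Lctl, lower in DKO.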

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

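The counts without the skeletal muscle list (27 higher, 7 lower) and the medians without saturated genes were chosen after seeing the data; the other alternatives were set before. The 27 follows from taking out Eno3 and Mb, and called muscle transcripts outside the list, such as Myom2, remain in it, so it does not count the muscle calls. Dim signal limits the calls: in simulation, split at the median intensity of changed probes (a split chosen after seeing the data), the rule found 3 of 22 dimmer and 28 of 28 brighter probes changed 3-fold, and 0 of 26 and 4 of 24 changed 2-fold. The count of genes higher was 53 with the scanner software's ratios and with the series value table, 96 at 1.5-fold and 7 at 3-fold; genes lower numbered 28, 28, 70 and 0 there, and 13 with offset 16. With 1 array alone, without dye balance, 32 to 55 were higher and 9 to 38 lower, and the 32 and 38 came from the same array. The 0 called genes near the targeted loci stayed 0 with windows of 5 and 20 Mb and became 1 with the software's ratios. Rora moved to −0.59 with offset 16 and −0.96 with the software's ratios and the value table, and ranged from −0.42 to −0.35 with 1 array alone. The lists of fatty acid and triglyceride synthesis, cholesterol, brown adipocyte, skeletal muscle and glucocorticoid genes kept their direction and stayed outside the central 95% in every setting run. Their sizes changed more: the cholesterol median was −0.0169 with median centring and −0.17 with the software's ratios. The muscle median was 0.50 with the software's ratios. The ROR response element median entered it with the software's ratios (−0.0281) and the value table (−0.0281), without the dim filter (−0.0131) and with the strict filter (−0.0249), turned to 0.0599 with median centring, and was −0.0753 to −0.0233 on single arrays. The fibroblast median entered it at −0.0328 with offset 16, −0.0388 with the software's ratios and the value table, −0.0266 with median signals, −0.0337 with loess on detected probes and −0.0166 without the dim filter, turned to 0.0216 with median centring (percentile 3.66), and was −0.0158 to −0.0038 on single arrays. Phase I and II entered it with median signals (0.0187) and median centring (0.11), and spanned −0.00075 to 0.0160 on single arrays, turning sign on one. The thyroid and adrenergic median entered it with median signals (0.0381) and median centring (0.14), and was 0.0420 to 0.0828 on single arrays. The brown adipocyte median was 0.11 with the software's ratios and 0.15 with median centring. On single arrays it spanned 0.0714 to 0.14, oxidative phosphorylation 0.0020 to 0.13, fatty acid oxidation 0.0789 to 0.27 and heat shock 0.0225 to 0.17. The settings with 1 array alone count genes as measured on that array only. Their list members or probes, and so their medians, can differ from the per-array medians given in the results. Median centring moved the median of all measured genes with a symbol to 0.0546, so a turn of sign under it is not specific to a list. The other causes were not tested. Of 803 values of named genes, 717 moved by less than the SD of both arrays, 86 moved by more and 0 changed sign among called genes. Part of that count was fixed in advance. With the same probe, leaving out 1 array moves a mean by less than that SD, and the dim filters leave it unchanged. Called genes have the same sign on both arrays by rule. The count therefore overstates stability.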

Other observations

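The tests on adipocyte share, dye bias and muscle carry-over were chosen after the results were seen; those on low-insulin genes, adrenergic genes and neighbouring genes were written before. The margins used to decide those (the SD of the arrays' medians, or counting error) were set after their values were seen; without a margin each value would lie on the side fixed for excluding the explanation. The genes in this paragraph lie outside the rule for named genes and were chosen after their values were seen. Ucp1, the uncoupling protein of brown fat, read 0.73 ± 0.00, its coactivator gene Ppargc1a 0.54 ± 0.04 and Ppara 0.61 ± 0.04. Acly (−0.99 ± 0.38), Me1 (−0.91 ± 0.17) and Scd2 (−0.91 ± 0.28) were the next lowest lipogenic genes after Acss2. Noct, the rhythmic gene nocturnin, read 0.93 ± 0.14, and the collagen chaperone Serpinh1 read −0.80 ± 0.04. Klf15, a glucocorticoid-induced transcription factor, was called at 1.10 ± 0.28, though its second probe read 0.17 ± 0.01. Probe A_51_P192042, annotated in the file as myosin heavy chain IIX, the product of Myh1, was called at 1.48 ± 0.15. It matched no symbol and so did not enter the muscle list. The probe matched to Myh1, which did, read 0.18 ± 0.09 and was dimmer (average log2 intensity 7.56 against 10.44). Probes annotated to this gene thus differed.

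The lower lipogenic genes in DKO were weighed against 3 explanations. A smaller share of adipocytes would lower shared adipocyte markers as much, but their median lay 0.46 above the lipogenic median. That is more than 0.37, the root sum of squares of the array SDs of both lists' medians (0.49 against 0.34 without saturated genes). Dye bias of bright probes would reverse between arrays, but both list medians were negative, the higher being −0.21, and the median of both arrays lay below all intensity-matched random lists. A low-insulin or fasting-like state may lower lipogenesis and raise FoxO targets: 18 such genes not looked at before had a median of 0.04, at percentile 96.99. That lies under the upper limit fixed beforehand, but by less than the SD of the arrays' medians, so this explanation stays open, as does an effect of the genotype, which these data did not test separately. By design the list left out genes whose values had been seen, called genes such as Pck1 and Pdk4 among them. Its median therefore does not weigh those genes.

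The higher thermogenic genes might reflect stronger cold or beta-adrenergic stimulation of the DKO mice. A list of 14 cAMP and adrenergic genes not looked at before had a median of 0.03, at percentile 94.18, under the limit fixed beforehand by less than the SD of the arrays' medians. This list too left out genes whose values had been seen, Dio2 among them. Gadd45g (0.77 ± 0.33) lay highest, then Ffar4 (0.58 ± 0.03), and Maff (−0.69 ± 0.01) lay lowest. Of the 14 genes, 4 lay above 0 on both arrays and 3 below 0 on both, so members went both ways. This explanation and an effect of the genotype stay open.

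The higher muscle genes could come from more muscle carried into the DKO preparation. Carry-over of the same muscle would raise fast and slow fibre genes alike only if both sets drew a like share of signal from muscle. That share was not measured, so a gap between the sets cannot decide against carry-over. The median of 11 fast-fibre genes exceeded that of 6 slow-fibre genes by 0.44. On the single arrays the difference was 0.53 and 0.56, with an SD of 0.02. That SD belongs to the single-array differences and is not the error of the 0.44, which comes from values averaged over arrays. The slow-fibre median was −0.09 on one array and 0.12 on the other, so the bound set for excluding carry-over was not met. Muscle of another fibre makeup was not tested.

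Flanking DNA of another strain beside the targeted genes would gather called genes there if it acted on the genes it carries. All 31 called genes with a position lay more than 20 Mb away, which is 86.1% of called genes (95% binomial limits 70.5% and 95.3%) even if the 5 without a position are counted as near, so that is not the cause of most calls; this test was chosen after the counts were seen. Whether such DNA adds a small local excess stays open: the share of called genes within 10 Mb was 0 times the share elsewhere, on an expected count of 0.84. Effects of such DNA on distant genes were not tested.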
